A study of Homo sapiens with 6 samples.

How the data were processed

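RNA sequencing was analysed in 6 libraries of MDA-MB-231 cells, 3 with a vector carrying DNAJC12 and 3 with the empty vector, grouped and numbered per the labels. The deposited tables held, for 58735 genes, the count of reads per gene in each library and the FPKM of each gene in each library, both made by the authors. Per the submitters' processing notes, reads were aligned with HISAT2 2.0.5 to hg19. The gene identifiers, symbols and coordinates of all 58735 genes equal those of GENCODE 29 on GRCh38, which disagrees with hg19, so coordinates are given as GRCh38. The program that counted reads and its strand setting are not given in the sources used here. Without the strand, values of antisense and overlapping genes are uncertain, as are those of near-identical copies such as PRSS2, CCL3L1, MAGEA3, MAGEA6 and histone genes. Each deposited FPKM equalled the count times 1e+09, divided by gene length and by 1 depth per library, which was 0.854 to 1.10 times the library's total count. Totals ran from 17967283 to 18887497 counts. Genes not tested held 0.129% of all counts.

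The groups were compared with the edgeR 4.0.16 quasi-likelihood test in R 4.3.3, with TMM normalization, a filter by filterByExpr (minimum count 10, minimum total 15) and robust dispersions. P-values were adjusted by the Benjamini-Hochberg method over 14520 genes, with a threshold of 0.05, and the common biological coefficient of variation was 26.6%. Fold changes are overexpression against empty vector. Log2 CPM for principal components and correlations used a prior count of 2. An exact permutation test of 3 against 3 libraries cannot go below a p of 0.1, so none was run on single genes. The interval of the DNAJC12 ratio is the exact Clopper-Pearson interval of the binomial share of counts.

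The groups, tests, alternatives, named-gene rule and 41 gene lists were fixed before the data were examined. Lists were tested with camera of limma 3.58.1 at a preset correlation of 0.01, adjusted over the 39 lists with at least 5 tested genes. The rule took DNAJC12 and, among called protein-coding genes with a mean of at least 5 CPM in the group where they are higher and no overlap between groups, the 10 largest changes and 5 smallest adjusted p in each direction. It also took up to 4 called members of each list, or the 2 most abundant members where fewer than 2 passed. Those 2 were named only for lists described in their own sentences. Another 25 genes were added after their values were seen, among them PSAT1, CHAC1, ASNS, MTHFD2, SHMT2, HERPUD1, CXCL2, EGLN3, ZFP36, MAP1LC3B, PECAM1, SLC7A11 and GPX4. Genes of neighbouring pairs and abundant markers of other cells were named for that place alone. Some genes that met the rule or were added are not reported here.

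Alternatives were DESeq2 size factors, the DESeq2 1.42.0 Wald test, no filter, a filter of 1 CPM in 3 libraries, a replicate block, leaving out each library in turn, library sizes without DNAJC12, and limma on log2 FPKM with pseudocounts of 1 and 0.1. The FPKM filter was 0.5 in 3 libraries, or none. A pseudocount on FPKM understates changes of genes with low values. For lists, camera with an estimated correlation and fry were run. After the data were seen, a GC correction (a loess trend of log2 CPM on transcript GC content in each library, span 0.3), a fit without both libraries numbered 2, and a fit with 1 surrogate variable (sva 3.50.0) were added. GC content came from GENCODE 29 transcripts and was known for 58676 genes. Tables and figures were made with Python 3.11.15, pandas 2.3.3 and matplotlib 3.10.9.

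The steps were tested on simulated data with 200 changed genes. With independent noise at the fitted dispersion, edgeR recovered 19% of genes changed 2-fold and 87.9% of those changed 4-fold, with 5.36% false calls. With the libraries' own GC trends it recovered 11% and 88% with 0 false calls, and after GC correction 71% and 97% with 7.18% false calls. The simulated trends came from the loess fit that the correction uses, with noise at the dispersion left after it. Better recovery after correction was thus built in, and it does not test the GC-corrected calls on the real data. In both simulations, each drawn once, camera recovered 10 of 10 changed sets and called 0 of 90 others. With an estimated correlation it recovered 8 and 6. A call lost with an estimated correlation can therefore reflect lower power. The simulated sets were random genes with independent noise. Estimated correlations of real lists reached 0.88 (mitochondrially encoded genes), so the 0 of 90 does not measure false calls of correlated lists.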

Results

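Transcript abundance was measured by RNA sequencing in 6 libraries of MDA-MB-231, an established human triple-negative breast cancer cell line. In 3 libraries the cells had been transfected with a vector carrying DNAJC12, and in the other 3 with the empty vector. DNAJC12 encodes a J-domain protein, a co-chaperone class that passes client proteins to heat shock chaperones, and its known clients include the aromatic amino acid hydroxylases. The comparison asked which transcripts differed between cells given DNAJC12 and cells given the vector alone. The overexpression libraries held 18340306, 18563750 and 18887497 counts and the empty vector libraries 18343249, 18069141 and 17967283. Between 20310 and 21971 genes had at least 1 count in a library, and 14520 genes were tested. The labels do not say that the libraries of a group came from separate cultures. P-values of single genes therefore measure only the spread between these samples, which may be technical. Camera compares the genes of a list with other genes, so its p-values at a preset correlation do not measure the spread between libraries.

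DNAJC12 itself was read in every overexpression library and almost absent with the empty vector. The gene (ENSG00000108176, minus strand of chromosome 10, 67796665 to 67838166 in GRCh38) had 522, 523 and 492 counts in overexpression replicates 1 to 3, and 1, 0 and 0 counts in the empty vector libraries. Its level was 28.3 ± 4.13 CPM (SD, n = 3) with the vector carrying DNAJC12, above 59.2% to 66.2% of the tested genes in those libraries. The ratio of CPM between the groups was 1550, with a 95% counting interval of 278 to 61255 from the exact binomial method, since the empty vector group held 1 count in all. Intervals and floors cover counting error only. In an empty vector library, a floor of 3 counts corresponded to 0.160 to 0.167 CPM. The edgeR quasi-likelihood test with Benjamini-Hochberg adjustment gave an adjusted p of 0.000116. Gene-level counts do not separate vector-derived from genomic DNAJC12 transcripts.

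The libraries differed within groups as well as between them. The first principal component of log2 CPM held 49.9% of the variance and placed overexpression replicate 2 at 46.8, against -64.0 and -29.6 for replicates 1 and 3. The empty vector libraries lay between them, at -1.85, 37.6 and 11. The second component held 31.8% and put all 3 overexpression libraries below 0 and all 3 empty vector libraries above it. Pearson correlations of log2 CPM ran from 0.936 to 0.985 among overexpression libraries and from 0.980 to 0.988 among empty vector libraries. The mean GC content of the counted transcripts was 51.1, 54.0 and 52.2% in overexpression replicates 1 to 3 and 52.0, 53.3 and 52.8% with the empty vector. Low-GC transcripts had lower counts in overexpression replicate 2: among the fifth of genes with the lowest GC content, its median gap to the mean of replicates 1 and 3 was -1.05 on the log2 scale, and among the fifth with the highest it was 0.73. Empty vector replicate 2 went the same way against replicates 1 and 3 of its group, less far, at -0.40 and 0.27.

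**Figure D1:**
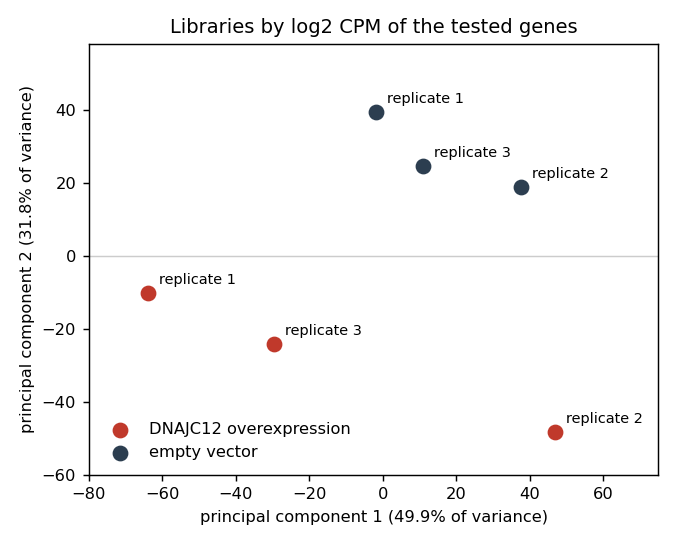
Each point is 1 library placed by its first and second principal components of log2 CPM over the tested genes, red for DNAJC12 overexpression and dark blue for the empty vector. Overexpression replicate 2 lies at 46.8 on the first component, far from replicates 1 and 3 of its group, while the second component separates the groups.

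Across all genes, 85 were higher and 96 lower with DNAJC12. After DNAJC12, the largest rises among called protein-coding genes with a mean of at least 5 CPM in the higher group and no overlap between groups were in PRSS2, a trypsinogen (log2 fold change 3.9 ± 0.36 SE), and TRIB3, a stress-induced pseudokinase (3.10 ± 0.26 SE, from 65.6 ± 4.78 to 563 ± 173 CPM, SD, n = 3). ALPK2, an alpha kinase, rose by 2.86, HKDC1, a hexokinase-domain protein, by 2.62 and ADM2, a peptide hormone of the calcitonin family, by 2.59. The largest falls among such genes were in BCL2A1, an antiapoptotic BCL2 relative (-4.51 ± 0.67 SE), and in the gel-forming mucins MUC5AC (-4.36 ± 0.34 SE) and MUC5B (-3.30 ± 0.31 SE). SERPINB2, an inhibitor of plasminogen activators, changed by -3.10, the pyrimidine nucleotide receptor P2RY6 by -2.64 and the NADPH oxidase NOX5 by -2.49. PRSS2 and the chemokine CCL3L1 (-2.65) have near-identical copies, so their counts are uncertain. Without overexpression replicate 3, ALPK2 (adjusted p = 0.0875), SERPINB2 (0.0505), CCL3L1 and P2RY6 (both 0.0875) were not called by the edgeR test. Without empty vector replicate 1, ALPK2 (0.0897), BCL2A1 (0.0931) and P2RY6 (0.0561) were not called, nor was ALPK2 without replicate 2 (0.0839) or 3 (0.0955).

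All 181 genes had an adjusted p under 0.05 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Of them 84 higher and 96 lower genes changed at least 2-fold, and 80 and 92 were protein coding. Without adjustment, 2048 genes had a p under 0.05. The groups did not overlap in 2919 genes, 20.1% of those tested, against 10% by chance. Genes share trends such as that with GC content, so the share in 1 split can lie far from 10% without a group effect. Overexpression replicates 1 and 3 with empty vector replicate 1, set against the other libraries, gave 4234 genes at an unadjusted p under 0.05 in the edgeR test. The number of calls depended on single libraries. It was 249 without overexpression replicate 1, 3366 without replicate 2 and 25 without replicate 3, and 25, 41 and 27 without empty vector replicates 1, 2 and 3. Each of those fits had 1 library fewer. A call lost there can reflect lower power and does not by itself show that 1 library drove the change. After a correction for GC content, chosen after the data were seen, 2582 genes were called, and without both libraries numbered 2 there were 2754. The DESeq2 Wald test called 523. In all 18 alternatives, each of the 181 genes that was tested had the same direction. Of 57 called genes followed through the alternatives besides DNAJC12, 36 were not called without overexpression replicate 3, and 37, 27 and 35 without empty vector replicates 1, 2 and 3. Over the fits without 1 library, log2 fold changes ran from 2.51 to 3.14 for ALPK2 and -5.55 to -4.01 for BCL2A1. They ran from -3.28 to -2.84 for SERPINB2, -2.89 to -2.43 for CCL3L1 and -2.97 to -2.48 for P2RY6.

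**Figure D2:**
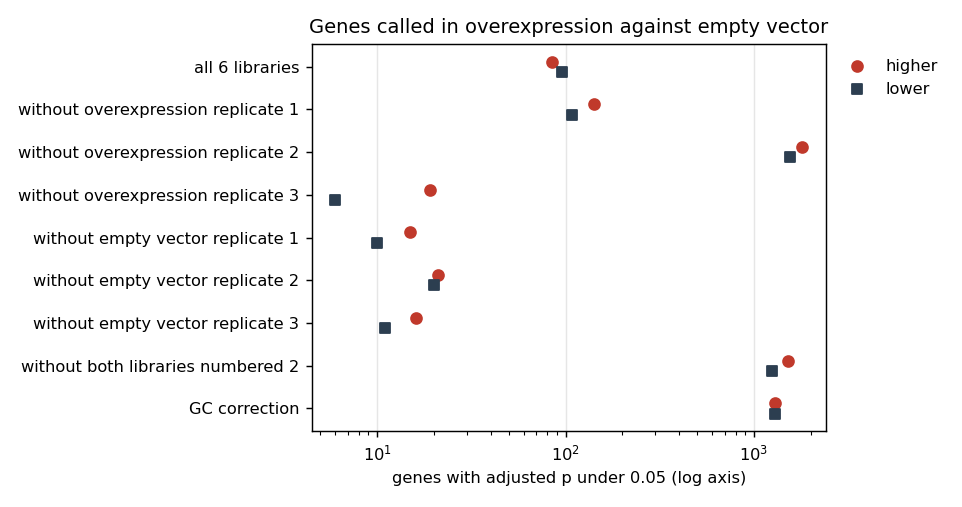
The number of genes with an adjusted p under 0.05 is plotted on a log axis for all 6 libraries, for each fit that leaves out 1 library, for the fit without both libraries numbered 2 and for the GC correction. Red circles are genes higher and dark blue squares genes lower with DNAJC12: 85 and 96 with all 6 libraries, 1806 and 1560 without overexpression replicate 2.

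Targets of the transcription factor ATF4, the effector of the integrated stress response, were higher with DNAJC12 as a group. Of 19 tested members, 9 rose, 10 did not pass the test and none fell, and all 19 had a fold change above 0. NUPR1, a stress-induced chromatin protein, went from 8.82 ± 1.60 to 62.2 ± 7.85 CPM (SD, n = 3), a log2 fold change of 2.82. PHGDH, the first enzyme of serine synthesis, rose by 2.70 and SESN2, a stress-induced inhibitor of mTORC1 signalling, by 2.19. The serine enzyme PSAT1 (2.15), asparagine synthetase ASNS (2.52), the glutathione-degrading enzyme CHAC1 (from 26.7 to 107 CPM) and the mitochondrial folate enzymes MTHFD2 (1.30) and SHMT2 (1.22) rose as well. Outside the list, CTH, which makes cysteine from cystathionine, and SLC1A4, a neutral amino acid transporter, rose by 2.81 and 2.67. MTHFD2 and SHMT2 were not called without overexpression replicate 3 or any 1 empty vector library (lowest adjusted p 0.180), nor was ASNS without overexpression replicate 3 (0.0575) or empty vector replicate 1 (0.0893) or 3 (0.0804). CHAC1 was not called without empty vector replicate 1 (0.0745) or 3 (0.0555). In the list, 15 members rose when adjusted over the list alone. The camera test gave an adjusted p of 1.32e-19, and 0.0197 with an estimated correlation. The number that rose was 17 without overexpression replicate 2 and 5 without empty vector replicate 1 or 3. It was 6 without overexpression replicate 3, 18 after GC correction and 16 without both libraries numbered 2.

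Cholesterol synthesis genes, under the control of SREBP, were also higher. Of 22 tested cholesterol synthesis genes, 3 rose and none fell, and all 22 had a fold change above 0, with a median log2 fold change of 0.97. INSIG1, which retains the SREBP complex in the endoplasmic reticulum, went from 59.5 ± 3.07 to 214 ± 22.5 CPM (SD, n = 3), a log2 fold change of 1.85. LSS, lanosterol synthase, rose by 1.44. Adjusted over the list alone, 14 members rose, and camera gave an adjusted p of 4.27e-11, and 0.0294 with an estimated correlation. The estimate for cholesterol genes was -0.002, also below the preset 0.01. Of 13 fatty acid synthesis genes, 1 rose, and 4 adjusted over the list alone. It was the stearoyl-CoA desaturase SCD, from 263 ± 12.5 to 1288 ± 56.7 CPM (SD, n = 3), a log2 fold change of 2.29. FASN, fatty acid synthase, had a log2 fold change of 0.78 and an adjusted p of 0.25 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. Camera gave the fatty acid list an adjusted p of 1.79e-05, lost at an adjusted p of 0.0749 with an estimated correlation. That correlation was -0.07, below the preset 0.01, so a higher correlation among members did not end the call. Without both libraries numbered 2, 15 cholesterol and 10 fatty acid genes rose. Without overexpression replicate 1, 7 and 3 of them rose, and without replicate 2, 15 and 9. Leaving out overexpression replicate 3 or any empty vector library left 1 cholesterol gene, and LSS was not called in these fits (lowest adjusted p 0.129). After GC correction, 17 and 10 genes rose.

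IL1B, the cytokine interleukin-1 beta, went from 217 ± 20.4 to 25.6 ± 1.45 CPM (SD, n = 3), a log2 fold change of -3.08 ± 0.21 SE. Of 23 tested NF-kB and inflammatory genes, 4 fell, 1 rose and 18 did not pass. The colony-stimulating factors CSF3 (-2.14) and CSF2 (-1.26) and the chemokine CCL20 (-2.30) fell with IL1B, whereas the neutrophil chemokine CXCL2 rose by 1.08. CSF3, CSF2 and CXCL2 were not called without overexpression replicate 3 (adjusted p = 0.0922, 0.196 and 0.272) or any 1 empty vector library (lowest adjusted p 0.0516), nor was CCL20 without overexpression replicate 3 (0.0819) or empty vector replicate 1 (0.0931) or 3 (0.0778). Adjusted over the list alone, 7 fell and 2 rose. As a group the list did not pass camera, with an adjusted p of 0.0550, and 0.259 with an estimated correlation. It did pass fry, which compares no list with other genes, at an adjusted p of 0.00224. The protease inhibitors PI3 (-3.08) and SLPI (-2.30) of mucosal secretions fell too, SLPI not without overexpression replicate 3 (0.108) or empty vector replicate 1 (0.0897) or 3 (0.0726). The list did pass camera without overexpression replicate 3 (adjusted p = 0.0415) or empty vector replicate 3 (0.0296), with a filter of 1 CPM (0.00967) and by limma on log2 FPKM (0.0039). Without overexpression replicate 1, 5 list members fell and 2 rose, without replicate 2, 7 and 3, after GC correction 9 and 6, and without both libraries numbered 2, 7 and 2. Of the list, 1 fell without overexpression replicate 3, and 1, 2 and 1 without empty vector replicates 1, 2 and 3, and in these 4 fits none rose.

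**Figure D3:**
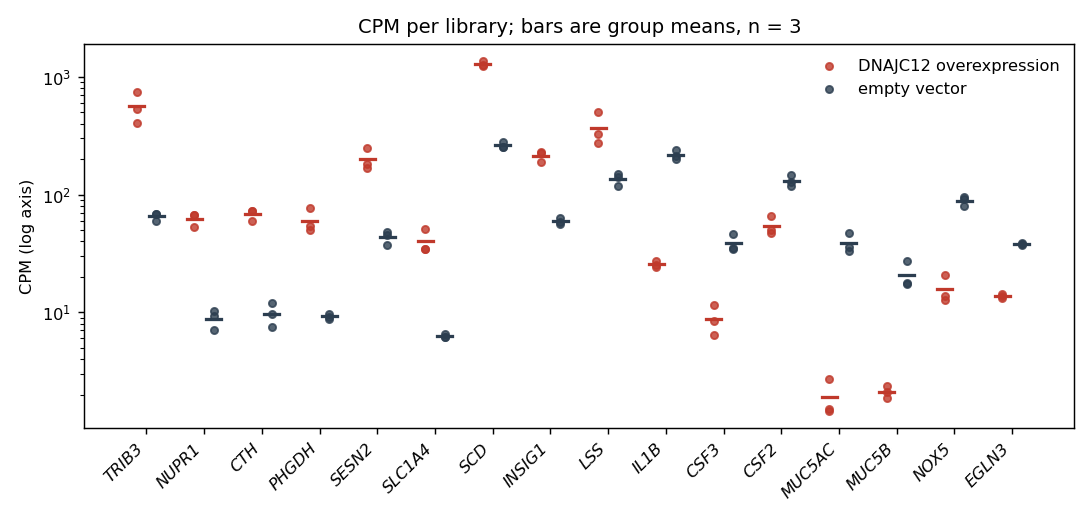
CPM of 16 genes is plotted on a log axis for each library, red for DNAJC12 overexpression and dark blue for the empty vector, with a short bar at each group mean (n = 3). TRIB3 to LSS lie higher with DNAJC12 and IL1B to EGLN3 lower, and in none of these genes do the groups overlap.

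Among ferroptosis suppressors, genes that limit lipid peroxidation, 2 of 21 rose and none fell. They were SCD and SLC3A2, the heavy chain of the cystine transporter (1.44), which was not called without overexpression replicate 3 (adjusted p = 0.143) or any 1 empty vector library (lowest adjusted p 0.106). Adjusted over the list alone, 3 rose. SLC7A11, the light chain of that transporter, had a log2 fold change of 2.46 ± 0.51 SE and an adjusted p of 0.0557 in the edgeR quasi-likelihood test with Benjamini-Hochberg adjustment. It lay above every empty vector library in all 3 overexpression libraries, at 80.5, 19.9 and 43.1 CPM against 8.10, 5.01 and 13. It passed without overexpression replicate 1 (adjusted p = 0.0291) and without replicate 2 (0.000273). The lipid peroxidase GPX4 had a log2 fold change of -0.02, with 0.17 and 0.04 without overexpression replicates 1 and 3 and 0.02 without empty vector replicate 2. Camera gave the suppressors an adjusted p of 0.0135, lost at an adjusted p of 0.150 with an estimated correlation and at 0.0532 without overexpression replicate 2. The estimated correlation was -0.04, below the preset 0.01. The number of suppressors that rose was 7 without overexpression replicate 2, with 1 that fell, 3 without replicate 1, and 1 without replicate 3 or any 1 empty vector library. After GC correction 7 rose and 1 fell. Of 20 ferroptosis promoters, CHAC1 rose, except without empty vector replicate 1 or 3, where none did, and adjusted over the list alone 3 rose and 1 fell. The promoters that rose were 7 without overexpression replicate 2 and 4 after GC correction, with 1 that fell in each. Their camera adjusted p was 0.141, and fry gave 0.0240.

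Apoptosis genes and AKT pathway genes did not pass camera as groups, and 3 apoptosis promoters and 1 suppressor were called. Of 21 apoptosis promoters, the BH3-only genes BMF (1.55) and BBC3 (1.68) rose, and another such gene, BIK (-1.50), fell, with the same counts when adjusted over the list alone. Of 10 apoptosis suppressors, BCL2A1 fell, also when adjusted over the list alone, while BCL2L1 and BIRC5 had log2 fold changes of 0.11 and -0.19. The list's median was 0.12, and -0.01 without overexpression replicate 1 and 0.06 without empty vector replicate 2, its mean -0.31 and its camera direction down, at an adjusted p of 0.641. Camera gave the promoters an adjusted p of 0.211, while fry gave 0.0311. BMF, BBC3 and BIK were not called without overexpression replicate 3 (adjusted p = 0.115, 0.159 and 0.245) or without any 1 of the empty vector libraries (lowest adjusted p 0.101). BCL2A1 was not called without empty vector replicate 1 (0.0931). With overexpression replicate 2 left out, 2 promoters rose and 3 fell, and 1 suppressor rose and 2 fell. None of 19 tested PI3K-AKT components passed, nor did any when adjusted over the list alone, and camera gave an adjusted p of 0.637. AKT1 and AKT2 had log2 fold changes of -0.04 ± 0.26 SE and 0.23 ± 0.26 SE. In the edgeR test 2 components were higher and 1 lower at an unadjusted p under 0.05, the DESeq2 Wald test called 1 higher and limma on FPKM none. Without overexpression replicate 2, 4 components rose and 2 fell, and after GC correction 3 rose and 2 fell. AKT1 had values above 0 without overexpression replicate 1 (0.14), overexpression replicate 3 (0.06) and empty vector replicate 2 (0.02), and AKT2 (-0.072) and BCL2L1 (-0.15) had values below 0 without overexpression replicate 2. None of 19 FOXO targets passed, and 2 rose and 2 fell when adjusted over the list alone. Of these targets 3 were higher and 2 lower at an unadjusted p under 0.05, DESeq2 called 1 and 2, and limma on FPKM none. Without overexpression replicate 1, 1 fell, and without replicate 2, 6 rose and 2 fell. Their camera adjusted p was 0.193, and CITED2 and TXNIP had log2 fold changes of 0.71 and 0.36.

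Heat shock chaperones, the partners of J-domain proteins, and the J-domain genes themselves gave no call. None of 20 heat shock response genes and none of 38 other J-domain genes passed, over all genes or adjusted over the list alone, with camera adjusted p of 0.158 and 0.641. The edgeR test put 2 heat shock genes lower, and 4 J-domain genes higher and 2 lower, at an unadjusted p under 0.05. DESeq2 called none of the former and 1 higher and 1 lower of the latter, and limma on FPKM none of either. The constitutive chaperones HSPA8 and HSP90AB1 had log2 fold changes of -0.49 and -0.29, and the J-domain gene DNAJB6 0.62. Of 20 genes of the endoplasmic reticulum unfolded protein response, HERPUD1 (1.16), which takes part in protein degradation there, rose, also when adjusted over the list alone. The chaperones HSPA5 and CALR had log2 fold changes of 0.65 and -0.53, and the list's camera adjusted p was 0.240. HERPUD1 was not called without overexpression replicate 3 (adjusted p = 0.184) or empty vector replicates 1 to 3 (0.199, 0.200 and 0.135). None of 8 tested aromatic amino acid hydroxylase and tetrahydrobiopterin genes passed, and the cofactor enzymes SPR and PCBD1 had values of -0.26 and -0.01. That list's camera adjusted p was 0.641, 1 member was lower at an unadjusted p under 0.05, and DESeq2 and limma called none. PCBD1 was at 0.11 without overexpression replicate 1 and at 0.01 without empty vector replicate 3. Without overexpression replicate 2, 2 heat shock genes fell, 6 J-domain genes rose and 2 fell, 8 unfolded protein response genes rose and 3 fell, and 1 hydroxylase or cofactor gene fell. After GC correction 4 heat shock genes fell. With 1 surrogate variable the heat shock list passed camera, lower, at an adjusted p of 0.0456.

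Hypoxia and glycolysis, DNA replication and mitotic genes were lower as groups by camera at the preset correlation, with adjusted p of 2.47e-06, 6.85e-06 and 0.0135. All 3 calls were lost with an estimated correlation, at adjusted p of 0.128, 0.0825 and 0.486. The estimates were 0.07, 0.02 and 0.20, above the preset 0.01. Hypoxia and glycolysis genes had a median log2 fold change of -0.47 with 8% of the 25 members above 0, and of -0.70 without overexpression replicate 2. The oxygen-sensing hydroxylase EGLN3 fell from 38.3 ± 0.77 to 13.8 ± 0.58 CPM (SD, n = 3), a log2 fold change of -1.47, and 6 members fell when adjusted over the list alone. The glycolytic enzymes ENO1 and GAPDH had values of -0.36 and -0.61. None of 24 DNA replication genes passed, 3 fell when adjusted over the list alone, and the median was -0.46, with MCM3 at -0.52 and MCM7 at -0.03. None of 24 mitotic genes passed either way, and the median was -0.26, with CDC20 at -0.67 and CCNB1 at -0.21. The mitotic median was -0.43 without overexpression replicate 1 and -0.15 without empty vector replicate 1, and CDC20 was at -1.03 without overexpression replicate 2. Of the replication and mitotic genes 12 and 3 were lower at an unadjusted p under 0.05, DESeq2 called 3 and 0 of them and limma on FPKM none. The mitotic call was also lost without overexpression replicate 2 (camera adjusted p of 0.208), without empty vector replicate 1 (0.0990) and without both libraries numbered 2 (0.0825). Without overexpression replicate 2, 15 hypoxia, 13 replication and 6 mitotic genes fell and 1 hypoxia gene rose, and after GC correction 12, 11 and 7. Without overexpression replicate 1, 2 hypoxia genes fell. EGLN3 was not called without overexpression replicate 3 (0.131) or empty vector replicates 1 to 3 (0.0917, 0.0877 and 0.113). MCM7 was at 0.12 and 0.03 without overexpression replicates 1 and 3 and at 0.02 without empty vector replicate 2.

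Replication-dependent histone genes and immediate early genes were higher as groups by camera at the preset correlation, with adjusted p of 6.79e-07 and 3.04e-05. Both calls were lost with an estimated correlation, at adjusted p of 0.0604 and 0.124. The estimates were -0.06 for the histones, below the preset 0.01, and 0.04 for the immediate early genes. Of 11 tested histone genes, HIST1H2BK (1.09) and HIST1H2AC (1.17) rose, and 8 when adjusted over the list alone. The list took 0.108 ± 0.00405% of all counts with DNAJC12 and 0.0667 ± 0.00211% with the empty vector (SD, n = 3). Histone genes are near-identical copies, so single members are uncertain. Of 20 immediate early genes, ZFP36 (1.26), which speeds the decay of cytokine mRNAs, rose, and 7 when adjusted over the list alone. DUSP1 and IER3 had values of 0.46 and 0.30. HIST1H2BK, HIST1H2AC and ZFP36 were not called without overexpression replicate 3 (adjusted p = 0.176, 0.181 and 0.165) or without any 1 of the empty vector libraries (lowest adjusted p 0.124). Without overexpression replicate 1, 4 histone genes rose, and without replicate 2, 8 histone and 8 immediate early genes, against 8 and 10 after GC correction. Targets of YAP and TEAD were higher (camera adjusted p = 0.0427) and matrix proteases lower (0.0403), with 0 of 14 and 0 of 16 members called by the edgeR test, and 0 and 1 adjusted over the list alone. Both were lost with an estimated correlation, at adjusted p of 0.354 and 0.445. At an unadjusted p under 0.05, 4 YAP and TEAD targets were higher and 4 matrix protease genes lower, DESeq2 called 1 and 0 of them, and limma on FPKM none. Leaving out overexpression replicate 1 ended both calls, at adjusted p of 0.0657 and 0.179, as did empty vector replicate 1 (0.159 and 0.0990) and replicate 2 (both 0.0505). The YAP and TEAD call also ended without overexpression replicate 2 (0.0628) or 3 (0.0743), and the matrix protease call with a filter of 1 CPM (0.0591), with 1 surrogate variable (0.0606), on log2 FPKM (0.0817) and after GC correction (0.115). Without overexpression replicate 2, 4 YAP and TEAD targets rose, and 6 matrix protease genes fell and 1 rose.

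**Figure D4:**
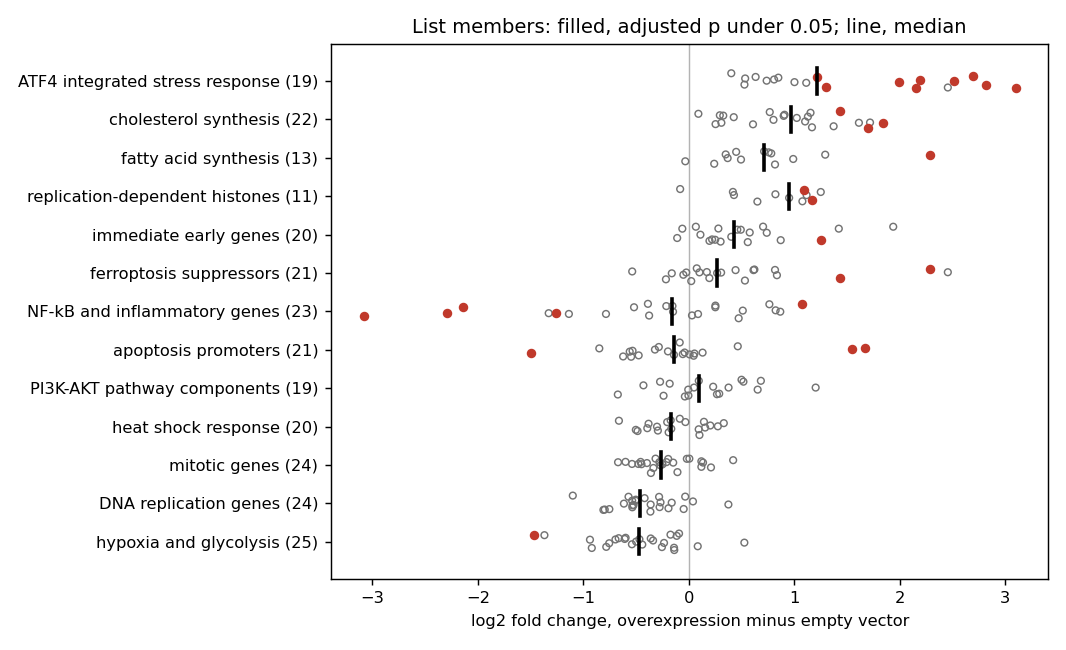
Each point is 1 tested member of a gene list, placed by its log2 fold change (overexpression minus empty vector), with the number of tested members in brackets. Filled points passed an adjusted p of 0.05 over all genes and black lines are list medians, 1.22 for the ATF4 list and -0.47 for hypoxia and glycolysis.

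With all 6 libraries, the other lists did not pass camera. Of 18 p53 targets, GDF15 (2.40), a stress-induced cytokine, and BBC3 rose, also when adjusted over the list alone, and camera gave an adjusted p of 0.294. Fry gave these targets an adjusted p of 0.0354. Without overexpression replicate 3 or any 1 empty vector library, 1 of them was called, GDF15, and without overexpression replicate 2, 4 targets rose and 2 fell. In the autophagy and lysosome list MAP1LC3B (1.32), a protein of autophagosome membranes, rose, also when adjusted over the list alone (camera adjusted p of 0.294). Of 23 extracellular matrix genes 1 fell and 22 did not pass, adjusted over the list alone 4 rose and 1 fell, and the camera adjusted p was 0.535. With overexpression replicate 2 left out, 5 matrix genes rose and 4 fell, and none was called without overexpression replicate 3 or any 1 empty vector library. MAP1LC3B was not called without overexpression replicate 3 (adjusted p = 0.165) or without any 1 of the empty vector libraries (lowest adjusted p 0.121), while 2 autophagy genes rose without overexpression replicate 1, and 3 rose and 3 fell without replicate 2. No member passed among NRF2 targets, in which FTL and FTH1, the ferritin chains, had log2 fold changes of 0.44 and 0.53, and 1 rose and 1 fell when adjusted over the list alone. Their camera adjusted p was 0.0550, and 0.293 with an estimated correlation, while fry gave 0.0453. The NRF2 list did pass camera in 6 alternatives: without overexpression replicate 1 (adjusted p = 0.00971), with 1 surrogate variable (0.0116), after GC correction (0.0156), on log2 FPKM (0.0241), with a replicate block (0.0453) and with a filter of 1 CPM (0.0498). Of its members 1 rose without overexpression replicate 1, 4 rose and 1 fell without replicate 2, and 6 rose and 1 fell after GC correction. No drug efflux transporter passed, with ABCA2 and ABCC1 at -0.22 and -0.18, and 1 fell when adjusted over the list alone (camera adjusted p of 0.569), while 1 rose and 3 fell without overexpression replicate 2. At an unadjusted p under 0.05 in the edgeR test, 4 NRF2 targets and 1 transporter were higher and 1 of each lower, DESeq2 called 1 NRF2 target higher and 1 transporter lower, and limma on FPKM none.

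Identity, signalling and housekeeping lists had no member past the edgeR test with all 6 libraries, but each had calls without overexpression replicate 2. There, 5 interferon-stimulated, 4 mesenchymal, 4 ERK feedback, 4 TGF-beta, 3 estrogen response, 3 stem cell, 1 epithelial and 1 ribosomal gene rose. In the same order 4, 3, 1, 2, 3, 2, 5 and 2 fell, as did 6 nuclear-encoded and 2 mitochondrially encoded respiratory chain genes. Camera adjusted p were 0.637 for epithelial genes, 0.154 for mesenchymal genes, 0.771 for interferon-stimulated genes, 0.336 for TGF-beta targets and 0.517 for ERK feedback genes. They were 0.569 for estrogen response genes, 0.517 for breast stem cell markers and 0.375 for cytosolic ribosomal proteins. For the respiratory chain they were 0.0874 for nuclear-encoded and 0.336 for mitochondrially encoded genes. Adjusted over the list alone, 3 mesenchymal and 1 ERK feedback gene rose, 1 TGF-beta target fell, 2 estrogen response genes rose and 1 fell, and 2 stem cell markers rose and 2 fell. At an unadjusted p under 0.05, counts in these lists ran from 0 for the nuclear-encoded respiratory chain to 5 interferon-stimulated genes higher and 5 epithelial genes lower. The DESeq2 Wald test called at most 3 genes in a direction in any of them, the mesenchymal genes, and limma on FPKM none. Some of these lists passed camera in an alternative. They were ribosomal proteins without overexpression replicate 1 (adjusted p = 0.0036), mesenchymal genes on log2 FPKM (0.0179) and mitochondrially encoded genes without both libraries numbered 2 (0.0303). The nuclear-encoded respiratory chain passed, lower, without overexpression replicate 2 (adjusted p = 0.00819), on log2 FPKM (0.0186), without both libraries numbered 2 (0.0193) and with 1 surrogate variable (0.0269). For epithelial genes and breast stem cell markers the median with all 6 libraries was above 0, and the mean and the camera direction were below it. The epithelial median was below 0 without overexpression replicate 2 (-0.06) or empty vector replicate 1 (-0.04), and the stem cell median without overexpression replicate 1 (-0.16) or empty vector replicate 2 (-0.06).

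Markers of other cell types gave 1 call. Of 6 endothelial markers, PECAM1, an adhesion molecule, fell by 1.99 on the log2 scale, also when adjusted over the list alone. No member of the luminal breast (12 tested), leukocyte (4), fibroblast (6) or neural and embryonic kidney (4) lists passed. Adjusted over the list alone, 1 luminal marker rose and 3 fell, 2 leukocyte markers rose, and 1 fibroblast marker rose and 1 fell. At an unadjusted p under 0.05 in the edgeR test, 1 luminal marker was higher and 4 lower, 2 leukocyte and 2 fibroblast markers were higher and 1 fibroblast marker lower, and 2 neural or kidney markers were lower. DESeq2 called 3 luminal markers lower, 1 leukocyte marker higher, and 1 fibroblast marker higher and 1 lower. Fry gave the endothelial markers an adjusted p of 0.0356. Camera gave adjusted p of 0.178 for endothelial, 0.517 for luminal and 0.910 for fibroblast markers, and the luminal median was 0.10 with a mean of -0.17. That median was -0.05 and 0.24 without overexpression replicates 2 and 3 and 0.05 without empty vector replicate 1. Lists with fewer than 5 tested members had no camera test. PECAM1 was not called without overexpression replicate 3 (adjusted p = 0.133) or empty vector replicate 1 (0.101) or 3 (0.0883). Without overexpression replicate 1, 1 leukocyte and 1 fibroblast marker rose, and without replicate 2, 3 luminal, 2 leukocyte and 1 fibroblast marker rose and 4, 1 and 2 fell, with 2 endothelial and 1 neural or kidney marker.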

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

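The GC correction, the fit without both libraries numbered 2 and the fit with 1 surrogate variable were chosen only after the results were seen. DNAJC12 stayed higher and past the threshold in all 18 alternatives, with log2 fold changes from 3.81 to 12.02 and adjusted p from 8.05e-90 to 0.00621. The numbers of genes higher, lower, higher by at least 2-fold and lower by at least 2-fold (85, 96, 84 and 96) were 265, 258, 205 and 211 by the DESeq2 Wald test and 366, 322, 277 and 273 with no filter. They were 1011, 926, 337 and 388 with a replicate block, 1288, 1294, 275 and 337 after GC correction, and 1514, 1240, 586 and 517 without both libraries numbered 2. With 1 surrogate variable they were 2346, 2372, 317 and 429, and by limma on log2(FPKM + 1) with no filter 8, 4, 8 and 4, where 27310 genes were tested. With a filter on FPKM, 58 genes were lower by at least 2-fold at a pseudocount of 1, which shrinks the folds of low genes. Leaving out 1 library gave 15 to 1806 higher and 6 to 1560 lower genes, and 15 to 777 and 6 to 536 by at least 2-fold. For the other changed counts the cause was not tested. DESeq2 size factors, a filter of 1 CPM and library sizes without DNAJC12 kept every count within 1.5 times. Among gene lists, 11 passed camera, 2 with an estimated correlation and 18 by fry, which compares no list with other genes, and 8 to 12 when 1 library was left out. The first principal component held 56.6% of the variance on log2(FPKM + 1) and 49.9% on log2 CPM, and the cause was not tested. Shared replicate numbers were checked for pairing. The within-group gaps correlated at r = 0.45, 0.58 and 0.03 across genes between libraries numbered 1, 2 and 3. Overexpression replicate 1 had -0.58 and 0.14 with empty vector replicates 2 and 3, and replicate 2 had -0.46 and -0.12 with 1 and 3. Overexpression replicate 3 correlated best with empty vector replicate 1 (0.22). Gaps within a group depend on each other, and both libraries numbered 2 shared a GC trend, so this check neither showed nor excluded pairing. The labels name no pairs, so the numbers were not treated as pairs. Genes are not independent replicates. Signs changed only in genes that were not called. Over the fits without 1 library, log2 fold changes ran from -0.36 to 0.14 for AKT1, -0.072 to 0.39 for AKT2, -0.15 to 0.27 for BCL2L1, -0.17 to 0.11 for PCBD1, -0.29 to 0.12 for MCM7 and -0.35 to 0.17 for GPX4. After GC correction PCBD1 was at 0.045 and MCM7 at 0.013, and without both libraries numbered 2 BCL2L1 was at -0.13, and the cause was not tested. In simulated data with 3 libraries a group, edgeR recovered 19% of 2-fold changes with independent noise at the fitted dispersion. With the libraries' GC trends it recovered 11%, and 71% after GC correction. The simulated trends came from the loess fit that the correction uses, so that gain was built in and does not test the GC-corrected calls.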

Other observations

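The gene lists in this part, the tests of GC content and transcript length between libraries, of neighbouring called genes and of aminoacyl-tRNA synthetases, and the GC correction were chosen only after the results were seen.

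Some enzymes that charge tRNAs in the cytosol were higher with DNAJC12. Of 20 cytosolic aminoacyl-tRNA synthetases, 7 rose, 13 did not pass and none fell, 15 had a fold change above 0 and 5 below, and 8 rose when adjusted over the list alone. WARS, for tryptophan, went from 190 ± 8.73 to 604 ± 84.5 CPM (SD, n = 3), a log2 fold change of 1.67, and AARS, SARS and GARS, for alanine, serine and glycine, rose by 1.45, 1.34 and 1.38. None of 17 mitochondrial synthetases passed the edgeR test, or an unadjusted p under 0.05, while 1 rose after GC correction and 1 fell without overexpression replicate 2. Of 17 amino acid transporters, 5 rose: SLC1A4 (2.67), the glycine transporter SLC6A9 (1.91), the glutamine carrier SLC1A5 (1.49), and SLC3A2 (1.44) and SLC7A5 (1.30), which form a transporter of large neutral amino acids. Adjusted over the transporter list alone 10 rose and 2 fell, and after GC correction 11 rose and 1 fell. Of 12 serine, glycine and one-carbon enzymes, 6 rose, among them CTH (2.81) and the phosphatase PSPH (1.30), which completes serine synthesis, and 4 members were also in the ATF4 list. Adjusted over the serine enzyme list alone 7 rose, and after GC correction 7 rose and 1 fell. After GC correction 11 cytosolic synthetases rose and 2 fell. These lists were drawn up after called genes had been seen, so their camera p-values are not given. Without overexpression replicate 2, 12 cytosolic synthetases, 10 transporters and 7 serine enzymes rose and 1 of each fell. With overexpression replicate 3 left out 1, 1 and 3 rose, and with empty vector replicates 1, 2 and 3 left out 0, 1 and 0 synthetases, 1, 2 and 1 transporters and 3 serine enzymes each time. WARS was not called without empty vector replicate 1 (adjusted p = 0.059) or 3 (0.0648). AARS, SARS, GARS, SLC1A5, SLC3A2, SLC7A5 and PSPH were not called without overexpression replicate 3 or any 1 empty vector library (0.0839 to 0.234), nor SLC6A9 without overexpression replicate 3 (0.0575) or empty vector replicates 1 (0.0931) and 3 (0.0899).

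Transcripts of some mucins and antiproteases and of a pair of cancer-testis antigens were lower. Of 10 mucins and antiproteases, 6 fell and none rose: MUC5AC, MUC5B, PI3, SERPINB2, SLPI and LCN2, an iron-siderophore binding protein that went from 126 ± 4.39 to 41.3 ± 9.88 CPM (SD, n = 3), a log2 fold change of -1.61. The list was drawn up around genes already seen to fall, so no list test is given. After GC correction or without overexpression replicate 2, 7 fell, without overexpression replicate 3, 3, and without empty vector replicates 1 to 3, 4, 5 and 4. MAGEA3 had 1, 0 and 0 counts with DNAJC12 and 19, 19 and 25 with the empty vector, and MAGEA6 had 0, 0 and 0 against 22, 17 and 15. They are near-identical copies, and the other 5 tested members of the family did not pass with all 6 libraries. After GC correction, and without overexpression replicate 2, 4 of the 7 fell. LCN2 was not called without overexpression replicate 3 (adjusted p = 0.108) or empty vector replicates 1 to 3 (0.0897, 0.0592 and 0.0804). MAGEA3 and MAGEA6 were not called without overexpression replicate 3 (both 0.0875), empty vector replicate 1 (0.0700 and 0.107) or 3 (0.0648 and 0.0726), nor MAGEA6 without replicate 2 (0.0688).

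Overexpression replicate 2 stood apart from replicates 1 and 3. Across genes its gap followed GC content (Spearman rho 0.797) and, more weakly, transcript length (rho -0.321, and -0.18 at equal GC content), so a GC-dependent difference in library preparation is a candidate explanation. Empty vector replicate 2 followed the same trend against replicates 1 and 3 of its group, with rho of 0.657 for GC content and -0.223 for length. Genes are not independent replicates. Markers of other cells had median gaps of up to 0.78 on the log2 scale, with KRT8 at 2857 CPM against 1398 and 1772 and CD74 at 718 against 402 and 523. Added cells and the GC trend cannot be told apart here, because the line itself expresses these markers.

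ATF4 targets were higher with DNAJC12. A GC trend as the whole cause is argued against by their median of 1.17 after GC correction, against 1.22 before. A single library is argued against by the median nearest to 0 when 1 library was left out, 1.03, without overexpression replicate 2. The synthetases outside the fixed list had a median of 0.86, and 0.46 without overexpression replicate 1, against -0.17 for mitochondrial ones, which was -0.27 without overexpression replicate 2 and -0.11 without empty vector replicate 1, but that list was drawn up after called genes had been seen, so it does not bear on whether the ATF4 response was wider. A difference between cultures other than DNAJC12 stays open and was not tested.

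The NF-kB list had 10 members above 0 and 13 below, with an SD of 1.08, so its median of -0.15 decides little. The median was -0.10 after GC correction, -0.28 and -0.061 without overexpression replicates 1 and 2, and -0.082 without empty vector replicate 2. GC content and a single library cannot be told apart from a difference between the groups for this list, because its members go both ways.

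Called genes lay next to each other more often than in permutations. There were 10 neighbouring pairs called in the same direction, 8 lower and 2 higher, against a median of 1 and a 95th percentile of 3 in 10000 permutations. They were MUC5AC with MUC5B, PI3 with SLPI, CST4, CST1 and CST2, MAGEA3 with MAGEA6, TRIB3 with RBCK1, ASB2 with OTUB2, PRKCE with EPAS1, and a run of CD24, C6orf203 and BEND3 on chromosome 6, all lower in that run. Several of these pairs are members of 1 gene family. The 172 other tested genes within 1 Mb that were not called had a median log2 fold change of 0.011 in the direction of the pair (95% bootstrap interval -0.10 to 0.09). This argues against a gain or loss of the regions around most pairs. Called genes were left out and all pairs were pooled, so a gain or loss at a few places could not show. The 10 pairs were counted after some had been seen, and neighbours of 1 family can share regulation. Clonal differences at a few places, or in the called genes alone, were therefore neither supported nor excluded.

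Of the 10 splits of the 6 libraries into 3 and 3, 1, the real one, called as many as 181 genes, and the highest of the others called 0. With 10 splits no share under 0.05 can be reached. The split that put overexpression replicates 1 and 3 with empty vector replicate 1 gave 4234 genes at an unadjusted p under 0.05, more than the 2048 of the real one, which points to a structure of the samples besides the groups. The libraries on that side had the lowest mean GC contents, at 51.1, 52.2 and 52.0%. The others had 54.0, 53.3 and 52.8%, and the cause was not tested.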
